A study of Mus musculus with 20 samples.

How the data were processed

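Total RNA of 20 macrophage samples from C57BL/6JRj mice was sequenced, 4 samples in each of 5 populations. The populations are dura macrophages with high and with low MHC class II, choroid plexus macrophages, microglia from the brain and peritoneal macrophages. The low-MHC II dura samples carry "int" in their titles and "lo" in their cell type label, and they are called MHC II-low here. The labels do not describe how the cells were isolated or handled, or whether the replicates of a population are separate animals. All p-values therefore measure the spread between these samples, which may be technical. The series text also names alveolar macrophages and Kupffer cells of another series, which were not analysed here.

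Per the labels, the authors used mm10 as the genome, and their notes list FastQC 0.11.4, Trimmomatic 0.38, TopHat2 2.1.0 and SAMtools 0.1.18. The counting program, the gene annotation and the strand setting are not given in the sources used here. The deposited unit is the count of reads per gene symbol, in whole numbers, for 24421 genes, with 5 further lines for reads given to no gene. Of the symbols, 23376 are in GENCODE release M21, whose build matches mm10 but which may not be the annotation the authors used. Positions, strands and exon overlaps were taken from that release, and 447 of the 450 genes considered for naming have a position there. Counts assigned to genes came to 13383274–32611875 per library. Reads in no feature made up 5.67–13.1% and ambiguous reads 0.836–1.51%. A level is given in CPM, counts scaled to 1e+06 TMM-adjusted gene counts per library. The floor of 3 counts corresponds to 0.0964–0.222 CPM in a single library. Counting intervals are 95% intervals, and intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

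The groups, the comparisons, the tests, the gene lists and the rule for naming genes were set before the data were examined. All 20 libraries were fitted together in edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr, which left 13960. TMM factors were 0.923–1.05, and the robust quasi-likelihood F test had 15 residual degrees of freedom. The common biological coefficient of variation was 0.302. P-values were adjusted over all genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05 and at least a 2-fold change. Positive log2 fold changes mean more in the population named first. A side made of several populations is the unweighted mean of their log2 levels. The dura side is the mean of both dura populations, and the brain side is the mean of all populations but the peritoneal one. A gene is specific to a population if called higher there than in each of the other 4, and shared by the border macrophages if called in one direction in both dura populations and in the choroid plexus, each against microglia.

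Genes were named by rule. Each comparison has the 8 genes with the largest fold change in each direction, at 20 CPM or more in the higher group and with no overlap between the libraries of the sides, and these are its largest rises and falls. Each population has its 6 specific genes with the largest smallest fold change, and the shared genes have 6 in each direction. Genes whose symbols mark clones, models, mitochondrial genes or pseudogenes were passed over. H2-Aa, H2-Ab1, H2-Eb1, Cd74, Tmem119, P2ry12, Sall1, Mrc1, Pf4, Ms4a7, Gata6 and Icam2 are given in all comparisons. Genes named from a list are among its largest changes at 10 CPM or more. Where a side has no counts, a fold is a bound against 3 counts summed over it, and with 1 to 3 counts it is a ratio of CPM with its interval. The higher side is the mean of the log2 levels of its populations, none taken under the floor of 3 counts. The fitted fold change of such a gene is not a bound.

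Gene lists were tested with camera in limma 3.58.1 on voom values, with the correlation between genes estimated for each list, against all other genes. Adjustment was over 32 lists in 5 comparisons. The 35 lists hold 402 genes, of which 400 are in the files and 368 were tested. Lists of macrophage genes cover microglia markers, border macrophage markers, large peritoneal macrophage markers, macrophage core genes, macrophage transcription factors, MHC class II, monocyte and dendritic cell markers, disease-associated microglia genes, complement, scavenger receptors, lysosome, iron and heme, cholesterol synthesis, lipid handling, TGF-beta signalling, oxidative phosphorylation, glycolysis, interferon response, inflammatory cytokines, immediate early and heat shock genes, proliferation and chemokine receptors. Lists of other cells cover choroid plexus epithelium, neurons, astrocytes, oligodendrocytes, fibroblasts, endothelium, B cells, T and NK cells, neutrophils, mast cells, erythroid cells and mesothelium. Some genes are in more than 1 list. The lists for T and NK cells, neutrophils and erythroid cells had fewer than 3 tested genes and are given as values without a test. With a preset correlation of 0.01 camera called 65 list tests, and 13 of these held with the estimated correlation. List counts are given over all genes and, where they differ, adjusted over the list alone.

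In the dura, samples of both populations with the same replicate number were more alike than others. After removal of each population's mean, the correlation across 8551 genes was 0.23 to 0.31 for the 4 pairs of the same number and −0.19 to 0.00 for the other pairs. Genes are not independent replicates. The pairs were therefore also fitted as a block. No other pair of populations showed this, and no library was a copy of another.

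Of 4-fold changes put into simulated counts, the procedure recovered 73.8% in the dura comparison and 73.8% for choroid plexus against microglia. It recovered 67.7% for dura against microglia, 81.0% for choroid plexus against dura and 80% for peritoneal macrophages. Of 2-fold changes, which lie at the threshold itself, it called 23.9%, 25.8%, 31.8%, 36.4% and 29.2%, and of 1.5-fold changes 1.49% for dura against microglia and 0 in the others. It made 4, 2, 2, 3 and 0 false calls in these. It found both changed lists and called 0 of 30 unchanged lists, which need not hold for correlated genes. In 10 simulations without any change the highest count of calls was 1.

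The alternatives tried were RLE normalization, no filter on low counts, a filter of 10 CPM in 4 libraries, no fold threshold, glmTreat against 1.5-fold, the Wald test of DESeq2 1.42.0, a replicate block, leaving out each library, fitting only the groups compared, single populations as the dura or brain side, and camera with the preset correlation. Chosen after seeing the data were a replicate block in the 8 dura libraries, libraries thinned to equal depth, subtraction of an epithelial part, and leaving out choroid plexus replicate 4 and microglia replicate 3 together. Subtraction of an epithelial part also left out microglia replicate 3, so the 2 steps are not told apart. Figures used matplotlib 3.10.9 under Python 3.11.15. Results that need items withheld for evaluation are not reported here.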

Results

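RNA sequencing covered macrophages of 3 brain compartments and of the peritoneal cavity. MHC II-high dura had 22203235–32611875 gene counts per library, MHC II-low dura 26312505–30398564, choroid plexus 13383274–16052955, microglia 15312617–17156227 and peritoneal macrophages 23532894–27948494. Each library had counts for 13111–15446 genes. The dura is the outer membrane around the brain, and the choroid plexus is the tissue that secretes cerebrospinal fluid. Levels are means ± SD in CPM, with n = 4 in each group. A value after a gene in parentheses is its log2 fold change. A second value after ± there is an approximate standard error, the size of the change over the square root of the F statistic. In a count's parentheses a library left out is given by population and replicate number.

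The 5 groups separated along the first components of a principal component analysis of the 1000 most variable genes, which carried 54.5%, 26.0% and 11.8% of the variance. Tmem119, a membrane protein of microglia, was at 5487 ± 771 CPM in microglia and at 878 ± 80.2 CPM in choroid plexus macrophages, the next highest group. Mrc1, the mannose receptor, was at 4614 ± 86.2 CPM in MHC II-low dura, 2922 ± 367 CPM in MHC II-high dura, 1837 ± 147 CPM in choroid plexus, 18.2 ± 1.82 CPM in microglia and 47.6 ± 15.9 CPM in peritoneal macrophages. Gata6, a transcription factor of large peritoneal macrophages, was at 172 ± 19.8 CPM in peritoneal macrophages and at most 4.69 ± 3.21 CPM elsewhere.

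**Figure D1:**
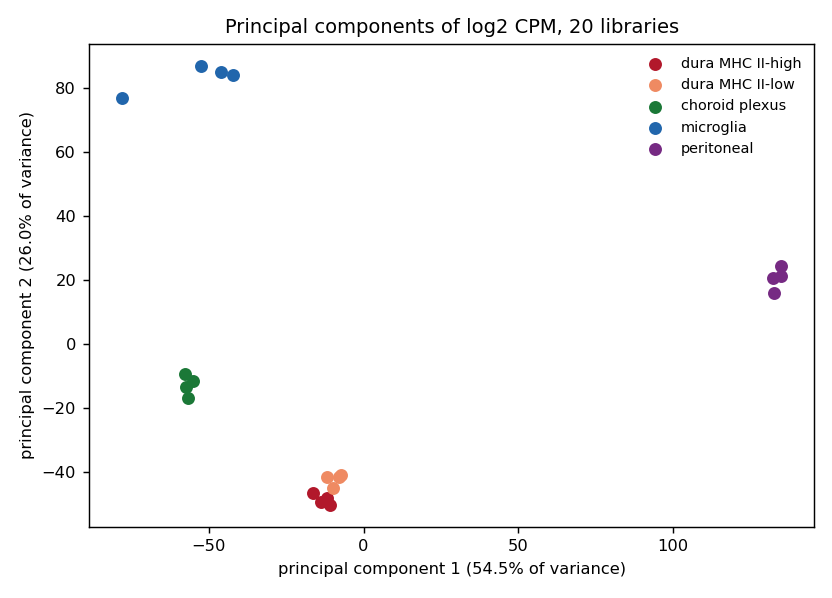
First and second principal components of log2 CPM of the 1000 most variable genes, with 1 point per library. The axes carry 54.5% and 26.0% of the variance, and microglia replicate 3 lies at −78.2 on the first, against −52.6 to −42.2 for the other microglia.

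**Figure D2:**
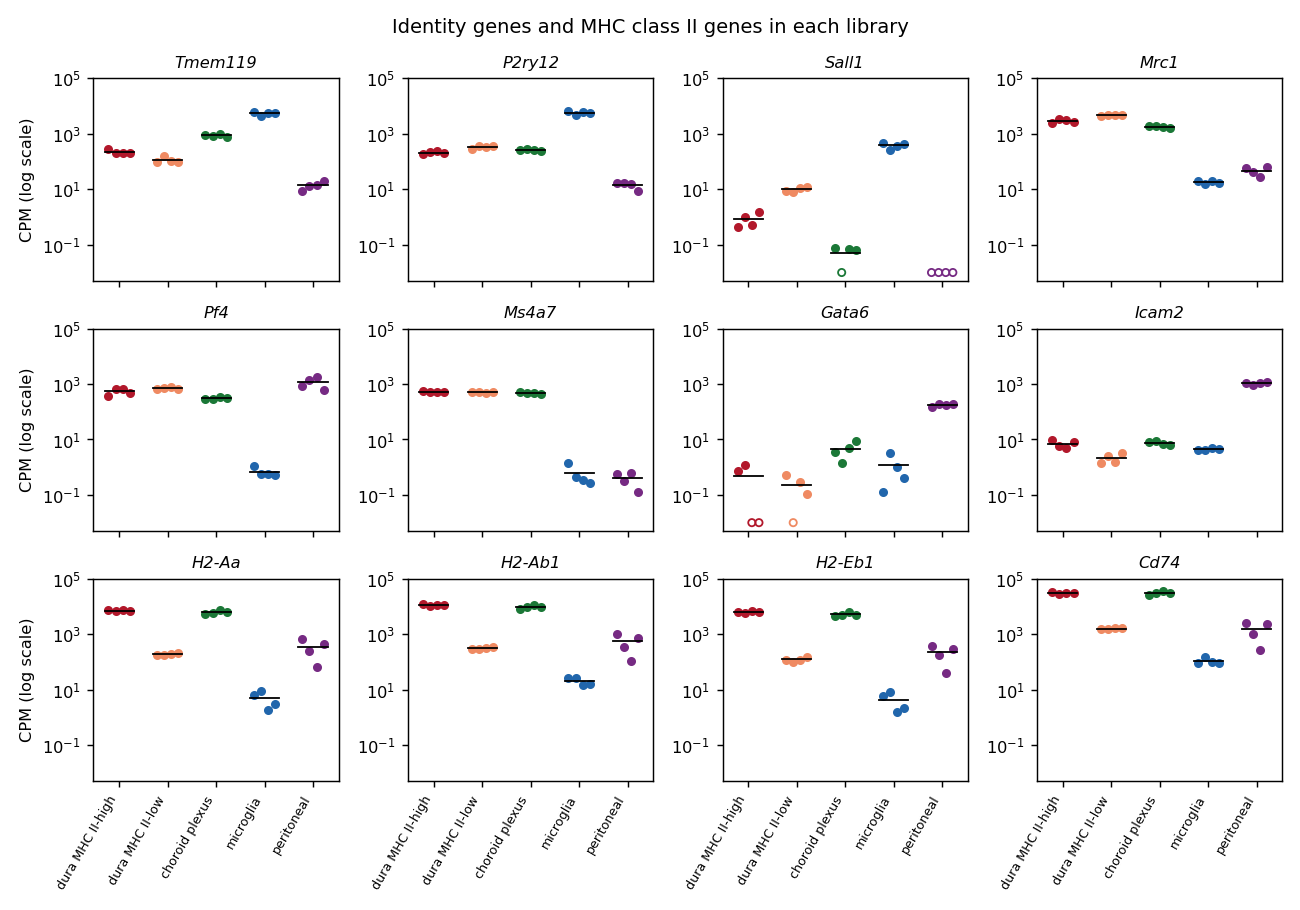
CPM on a log scale of identity genes by population, with 1 point per library and open symbols at the bottom for libraries without counts. Tmem119 has its highest mean, 5487 CPM, in microglia, and Gata6 its highest, 172 CPM, in peritoneal macrophages.

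The genes given in all comparisons are protein-coding. In mm10 coordinates they lie on chromosome 17 (H2-Aa 34282744–34287823, H2-Ab1 34257689–34269419 and H2-Eb1 34305867–34316674), 18 (Cd74 60803848–60812652 and Gata6 11052064–11085635), 5 (Pf4 90772435–90773383 and Tmem119 113793729–113800516), 3 (P2ry12 59216272–59262871), 8 (Sall1 89027235–89044162), 2 (Mrc1 14229392–14332057), 19 (Ms4a7 11321039–11336146) and 11 (Icam2 106377656–106388075). Of other genes named below, annotated exons of other genes cover 63.1% of the exon length of Folr2, 68.7% of Itgam, 34.4% of Ctsd and 49.1% of Kcnj13, so their values are uncertain, as are those of the closely related genes of the H2, Cd209 and Ccl families.

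The first comparison asks which genes part MHC II-high from MHC II-low macrophages of the dura, besides the MHC class II genes that define these groups. MHC II-high cells had more of Ccr2, a chemokine receptor of monocytes, with 1132 ± 87.9 against 106 ± 19.6 CPM, and of Retnla, a secreted resistin-like protein, with 70.9 ± 12.04 against 5.89 ± 2.05 CPM. MHC II-low cells had more of the hyaluronan receptor Lyve1, with 351 ± 48.1 against 94.95 ± 24.2 CPM, and of the iron exporter Slc40a1, with 1052 ± 147 against 252 ± 97.6 CPM. They also had more of Sall1 and Adgrg1, a transcription factor and an adhesion receptor typical of microglia, at 9.92 ± 1.94 against 0.855 ± 0.491 CPM and 24.1 ± 5.71 against 1.98 ± 0.855 CPM.

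In edgeR, 541 of 13960 genes changed, 334 of them higher and 207 lower in MHC II-high cells. The largest rises were those of the MHC class II genes H2-Eb1 (5.68 ± 0.58), H2-Aa (5.26 ± 0.57), H2-Ab1 (5.19 ± 0.48) and Cd74 (4.29 ± 0.47), and of their activator Ciita (4.04 ± 0.57). Gbp2b, a guanylate-binding protein, followed (3.71 ± 0.96, edgeR adjusted p = 0.0239), then Retnla (3.59 ± 0.42, adjusted p = 8.14e-05) and Ccr2 (3.41 ± 0.35, adjusted p = 6.44e-06). The call of Gbp2b was lost without MHC II-high replicate 2 (adjusted p = 0.0518) and without MHC II-low replicate 2 (0.0761), 3 (0.0776) or 4 (0.0514). The largest falls in edgeR at 20 CPM or more were those of Adgrg1 (−3.63 ± 0.34, adjusted p = 8.2e-06), the Wnt receptor Fzd8 (−2.87 ± 0.30), Nrap (−2.71 ± 0.25, adjusted p = 8.54e-07), the crystallin Crybb1 (−2.56 ± 0.37), the growth factor Tgfa (−2.53 ± 0.31), Angptl7 (−2.41 ± 0.28), Dock9 (−2.40 ± 0.36) and Egfl7 (−2.30 ± 0.25). In all of these genes every MHC II-high library lay on one side of every MHC II-low library.

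Sall1 fell (−3.54 ± 0.30) and the adhesion molecule Icam2 rose (1.73 ± 0.22, edgeR adjusted p = 2.54e-05) in MHC II-high cells. Tmem119 stayed short of 2-fold (0.97 ± 0.20) and was called without MHC II-high replicate 2 (1.01) or 4 (1.01), or without MHC II-low replicate 2 (1.20). The ADP receptor P2ry12 (−0.70 ± 0.15) and Mrc1 (−0.66 ± 0.17) were also short of 2-fold, with edgeR adjusted p values of 0.00391 and 0.015. Pf4 (−0.41 ± 0.24), Ms4a7 (0.03 ± 0.20) and Gata6 (1.14 ± 1.19) were not called, with edgeR adjusted p values of 0.328, 0.959 and 0.619.

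All 10 MHC class II genes rose, with a median log2 fold change of 3.51 and a camera adjusted p = 0.0206. Of 12 scavenger receptors, Colec12 (−2.19) and Stab1 (−1.13) fell and 10 were not called, with a median of −0.42 and a camera adjusted p = 0.0268. Of 18 microglia markers 5 fell, among them Sall1, Crybb1 and the sugar transporter Slc2a5 (−3.75, and −4.73 without MHC II-high replicate 1), and 6 fell adjusted over the list alone, with a median of −0.74 and camera adjusted p = 0.136. Of 18 border macrophage markers, Lilra5 (1.13) rose and 2, Lyve1 (−1.89) and Stab1, fell, with a median of −0.55 and camera adjusted p = 0.0539. That list was called with a replicate block (adjusted p = 0.00493) and without MHC II-high replicate 3 (0.0381) or 4 (0.0323), choroid plexus replicate 4 (0.0475) or microglia replicate 1 (0.0407). Of 12 iron and heme genes 1, Slc40a1 (−2.06), fell, with a median of −0.33 and camera adjusted p = 0.134, against 0.0167 with a replicate block.

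Of 13 dendritic cell markers (median 1.40) 4 rose, among them Itgax (2.58), and 2 fell, among them Fscn1 (−1.59), or 7 and 2 adjusted over the list alone. Of 12 monocyte markers (median 0.30) 2 rose, Ccr2 and S100a6 (1.77), and 1 fell (0 without any MHC II-high library or MHC II-low 2 or 4), or 3 and 1 adjusted over the list alone. Of 16 disease-associated microglia genes 3 rose, among them Itgax and Lgals3 (1.93), with 1 more lower without MHC II-high replicate 1 or adjusted over the list alone and a median of 0.49. Of 9 chemokine receptors (median 0.63) 1 rose, or 2 adjusted over the list alone. Of 22 macrophage transcription factors (median 0.06) 1 to 3 rose with single libraries left out, and 2 with all, among them Runx3 (2.18), and 2 fell. Of 18 large peritoneal macrophage markers (median 0.47) 1 rose (2 without MHC II-high 1) and 2 fell. Of 10 complement genes (median −0.16) C3 (1.21) rose. Of 18 lysosome genes (median −0.20) 2 fell (1 without MHC II-high 1 or 4 or MHC II-low 3), among them Ctsd (−1.10). Of 13 genes of TGF-beta signalling (median 0.46) at most 1 rose, of 12 proliferation genes (median 0.71) at most 3, and of 15 inflammatory cytokines (median 0.01) at most 1 rose and 2 fell, with all libraries or without any 1. Camera adjusted p values were 0.294, 0.437, 0.252, 0.13, 0.954, 0.946, 0.726, 0.605, 0.615, 0.615 and 0.946 in the order of these lists.

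Neither edgeR nor DESeq2 called a gene among 12 macrophage core genes, 16 of cholesterol synthesis, 13 of lipid handling, 18 of oxidative phosphorylation, 15 of glycolysis, 14 of the interferon response and 14 immediate early and heat shock genes. At an unadjusted p under 0.05 edgeR gave 4 core genes, 2 of them higher and 2 lower, 1 lipid gene in each direction, 1 oxidative phosphorylation gene higher, and 3 glycolysis genes higher and 1 lower, but 0 genes of the other lists. EdgeR called 1 glycolysis gene higher without MHC II-high replicate 1, MHC II-low replicate 1 or 4, peritoneal replicate 4, choroid plexus replicate 1 or microglia replicate 3 or 5. Their medians were 0.09, −0.05, −0.06, 0.15, 0.22, 0.06 and −0.04, with camera adjusted p values of 0.851, 0.946, 0.946, 0.799, 0.714, 0.946 and 0.936. Of the lists of other cells, 2 of 8 endothelium genes rose (4 without MHC II-high 2 and 1 without MHC II-low 3), or 4 adjusted over the list alone, with a median of 1.89 and camera adjusted p = 0.169. EdgeR called no gene of the lists of choroid plexus epithelium (13 genes, median 0.41), neurons (5, −0.01), astrocytes (8, −0.37), oligodendrocytes (7, 0.14), fibroblasts (8, 0.89), B cells (6, 1.51), mast cells (3, −0.28) and mesothelium (4, −0.23, or −0.01 with genes without counts at their bound). The adjusted p values of camera of these were 0.946, 0.946, 0.851, 0.851, 0.713, 0.772, 0.978 and 0.946. At an unadjusted p under 0.05 edgeR gave 1 neuron gene lower, 2 astrocyte genes lower, 1 B cell gene higher and 1 mesothelium gene higher, and DESeq2 called 1 neuron gene lower and 1 mesothelium gene higher. The 1 tested T and NK cell gene had a log2 fold change of 2.81 and was higher adjusted over the list alone, the 2 neutrophil genes a median of −0.63 and the 1 erythroid gene 0.80, none of them called over all genes. Without MHC II-low replicate 4 edgeR called the T and NK cell gene and 1 B cell gene higher, without MHC II-high replicate 1 it called 1 astrocyte gene lower, and without microglia replicate 3 it called 1 mesothelium gene higher. Median, mean and camera direction differed in sign for large peritoneal markers, transcription factors, cholesterol synthesis, lipid handling, interferon response, cytokines, neurons, oligodendrocytes, mast cells and mesothelium.

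**Figure D3:**
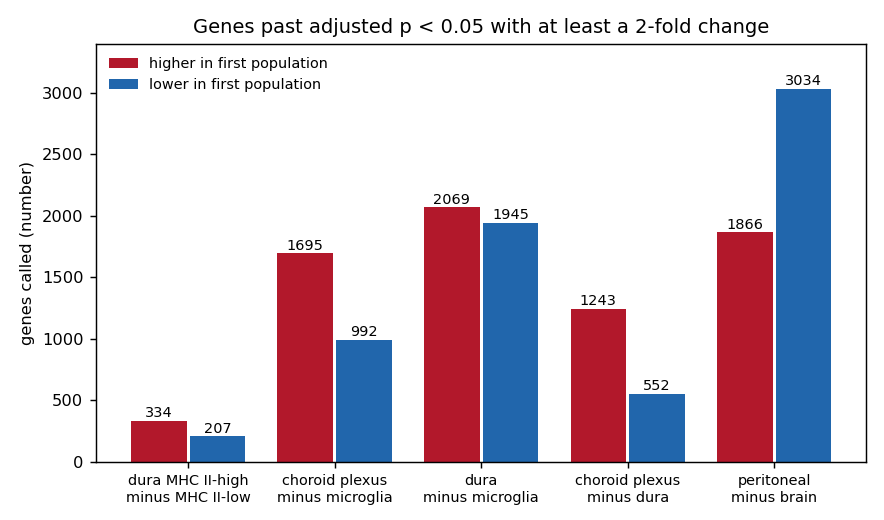
Number of genes called higher and lower by edgeR in each comparison, as bars from 0. The comparison of peritoneal with brain macrophages has the most called genes, 4900, and that of the dura groups the fewest, 541.

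The next comparison asks how choroid plexus macrophages differ from microglia, which lie in the brain tissue itself. Choroid plexus macrophages had 30278 ± 4511 CPM of Cd74, the MHC class II invariant chain, against 108 ± 25.3 CPM in microglia, and 43649 ± 2966 CPM of the lipid carrier Apoe against 1029 ± 172 CPM. Microglia had 98.9 ± 6.74 CPM of the uroplakin Upk1b and 44.6 ± 2.93 CPM of Csmd3, both without counts in choroid plexus macrophages.

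In edgeR, 2687 genes changed, 1695 of them higher and 992 lower in choroid plexus macrophages. The largest rises were those of Vnn3, at least 462-fold higher, and of Tlr8, Slfn1 and Chp2, which had 3, 2 and 2 counts in all microglia. Their ratios were 2088 (95% interval 715–10126), 979 (271–8081) and 946 (262–7814). Without microglia replicate 1 Tlr8 had no counts there and was at least 1572-fold higher, and without replicate 5 Slfn1 had none, at least 499-fold, and Chp2 had a ratio of 1449 (260–57229). H2-Aa (10.26 ± 0.71), H2-Eb1 (10.22 ± 0.71), Clec12a (10.13 ± 0.48, edgeR adjusted p = 6.9e-12) and Plbd1 (9.72 ± 0.51, adjusted p = 4.3e-11) also rose, Plbd1 by 10.57 without microglia replicate 3. The largest falls were those of Upk1b, at least 1951-fold lower, Csmd3, at least 879-fold lower, and the protease Adamts16, at least 526-fold lower. Sall3, Sall1 and Tmc7 had 1, 3 and 1 counts in all choroid plexus libraries, and their levels in microglia were 11049 (95% interval 1983–436398), 7650 (2618–37096) and 1885 (338–74442) times those. Without choroid plexus replicate 2 Sall3 had no counts there and was at least 2740-fold lower, and without replicate 4 Tmc7 had none, at least 461-fold. Slco4a1 (−9.32 ± 0.94, edgeR adjusted p = 3.32e-07) fell, with 2 counts and a ratio of 1478 (409–12202) without choroid plexus replicate 4, as did Adgrg1 (−8.73 ± 0.40, adjusted p = 1.03e-10).

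H2-Ab1 (8.90 ± 0.57), Cd74 (8.13 ± 0.56), Mrc1 (6.66 ± 0.22), Pf4 (8.80 ± 0.38) and Ms4a7 (9.62 ± 0.31, and 10.34 without microglia replicate 1) rose, with edgeR adjusted p = 1.9e-09 or less. Tmem119 (−2.64 ± 0.21) and P2ry12 (−4.48 ± 0.17) fell, with edgeR adjusted p = 3.74e-09 and adjusted p = 4.11e-14. Icam2 (0.81 ± 0.22) was short of 2-fold. Gata6 was not called (1.98 ± 0.79, edgeR adjusted p = 0.0541) and was called without choroid plexus replicate 2 (0.0325), microglia replicate 3 (0.00923), or MHC II-high dura replicate 2 (0.0485) or 4 (0.0437), and with a filter of 10 CPM (0.0479).

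All 18 border macrophage markers rose, with a median log2 fold change of 5.69 and a camera adjusted p = 0.00114, among them the hemoglobin receptor Cd163 (9.31) and the coagulation factor F13a1 (9.20). Without microglia replicate 1 these were 10.46 and 10.14. Of 18 microglia markers 17 fell and 1 was not called, with a median of −4.24 and a camera adjusted p = 0.00174. Of 12 scavenger receptors 8 rose, among them Cd36 (8.03) and Msr1 (6.06), with a median of 3.56, or 2.63 with genes without counts at their bound, and a camera adjusted p = 0.0465. That call was lost without MHC II-high dura replicate 1 (0.0561), MHC II-low dura replicate 3 (0.0549), peritoneal replicate 4 (0.0559) or microglia replicate 3 (0.0645), with a filter of 10 CPM (0.0742), in libraries thinned to equal depth (0.0538) and after subtraction of an epithelial part (0.059).

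Of 13 lipid handling genes 7 rose and 2 fell, or 8 and 2 adjusted over the list alone, with a median of 1.55 and a camera adjusted p = 0.107, against 0.0446 without peritoneal replicate 2. Of 12 iron and heme genes 4 rose and 2 fell, with a median of 0.74 and a camera adjusted p = 0.205, against 0.0467 with a replicate block. Of 10 MHC class II genes (median 5.13) 7 rose and 1 fell. Of 16 disease-associated microglia genes (median 0.80) 6 rose, among them Apoe (5.41) and Igf1 (6.47), and 5 fell. Of 15 inflammatory cytokines (median 2.87) 9 rose, among them Ccl7 (6.95) and Il1b (4.63), and 2 fell. Of 12 proliferation genes (median 2.51) 11 rose, and of 14 interferon response genes (median 2.01) 7 rose (4 without microglia 1 or 4, and 14 without microglia 5, which had 1455 summed CPM of them against 155–209), or 10 adjusted over the list alone. Of 12 monocyte markers (median 0.98) 4 rose, among them Lyz2 (5.38) and Ccr2 (5.06), and 1 fell. Of 13 dendritic cell markers (median 1.13) 6 rose, among them Mgl2 (8.50), and 3 fell. In camera, adjusted p values were 0.605, 0.625, 0.714, 0.714, 0.625, 0.714 and 0.772 from MHC class II to dendritic cell markers.

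Of 22 transcription factors (median 0.70) 8 rose and 4 fell, or 9 and 4 adjusted over the list alone. Of 10 complement genes (median 1.49) 6 rose. Of 18 lysosome genes (median −0.17) 1 rose (0 without choroid plexus 1 or 3 or microglia 3 or 5) and 3 fell, among them Ctsd (−3.12). Of 13 TGF-beta signalling genes (median −0.54) 3 fell (and 1 rose without microglia 3), among them Smad7 (−3.11). Of 14 immediate early and heat shock genes (median −0.30) 3 rose and 2 fell (1 without choroid plexus 1 or 4). Of 18 large peritoneal markers 2 rose (5 without microglia 3) and 3 fell, with a median of 0.68, or 0.28 with genes without counts at their bound. Of 12 core genes (median 0.22) 2 rose and 2 fell. Of 9 chemokine receptors (median 0.16) 3 rose and 1 fell (0 without choroid plexus 4), of 16 cholesterol synthesis genes (median 0.22) 3 rose, and of 15 glycolysis genes (median −0.09) 2 rose (1 without any library but microglia 3, since Pfkp had adjusted p = 0.0561–0.128, and 3.97 without microglia 3) and 2 fell, among them Slc2a1 (−1.59). Adjusted p values from camera were 0.772, 0.387, 0.723, 0.512, 0.851, 0.946, 0.946, 0.778, 0.768 and 0.851 in the order of these lists. Neither edgeR nor DESeq2 called any of 18 oxidative phosphorylation genes, of which edgeR gave 12 higher and 1 lower at an unadjusted p under 0.05 and called 4 higher without microglia replicate 3, with a median of 0.42 and a camera adjusted p = 0.726.

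Microglia replicate 3 had 21389 summed CPM of 13 choroid plexus epithelium genes, against 70.6–738 in the other microglia and 4154–7840 in the choroid plexus libraries. EdgeR and DESeq2 called 0 of the 13, and edgeR gave 0 at an unadjusted p under 0.05, with a median of 0.15. Without microglia replicate 3 all 13 were called higher in choroid plexus, among them Kcnj13 (4.04). Of 8 fibroblast genes (median 3.59) 7 rose, or 8 adjusted over the list alone. Microglia replicate 3 had 127 summed CPM of them against 8.66–21.1, and without it Col1a1 rose by 8.43, against 4.40. Of 8 endothelium genes (median −0.63) 1 rose and 2 fell. At most 2 in either direction, with all libraries or without any 1, were called of 3 mast cell genes (median 5.56, or 2.49 with genes without counts at their bound), 5 neuron genes (−0.42), 8 astrocyte genes (0.53), 7 oligodendrocyte genes (−0.71) and 4 mesothelium genes (−0.02). EdgeR and DESeq2 called 0 of 6 B cell genes, and edgeR gave 1 higher at an unadjusted p under 0.05, with a median of 1.60, or 1.54 with genes at their bound. With camera, adjusted p values were 0.696, 0.46, 0.625, 0.714, 0.772, 0.786, 0.851, 0.946 and 0.815 in the order of these 9 lists. The T and NK cell gene (0.00) and the neutrophil genes (median −1.97, or −0.35 at the bound) were not called, and the erythroid gene rose (3.75, not called without choroid plexus 3). Median, mean and camera direction differed in sign for immediate early and heat shock genes and for astrocytes.

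Dura macrophages were compared with microglia by the same question, with both dura groups averaged. Dura macrophages had 4225 ± 287 CPM of F13a1 in the MHC II-low and 2901 ± 341 CPM in the MHC II-high group, against 0.748 CPM in microglia. Cd209f, a C-type lectin, was at 433 ± 52.1 and 253 ± 29.1 CPM and had no counts in microglia.

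In edgeR, 4014 genes changed, 2069 of them higher and 1945 lower in the dura. The largest rises were those of Cd209f, at least 7124-fold higher, the matrix protease Mmp9, at least 4653-fold, Cd209g, at least 2222-fold, and Retnla, at least 440-fold. Rgs18 and Clec4n had 1 and 3 counts in all microglia, and ratios of 6330 (95% interval 1136–250014) and 5155 (1764–24999). Rgs18 had no counts without microglia replicate 1, at least 1589-fold higher, and Clec4n none without replicate 3, at least 3862-fold. The chemokine Ccl8 (12.74 ± 0.68) and F13a1 (12.19 ± 0.45) rose, with edgeR adjusted p = 3.91e-11 and adjusted p = 3.74e-14. Without microglia replicate 1 F13a1 had 13.14, and Ccl8 had no counts there and was at least 7495-fold higher. The largest falls were those of Csmd3, at least 3178-fold lower, Myo18b, at least 1438-fold lower, Nav3 (−10.70 ± 0.61), Chst8 (−9.62 ± 0.65), Sall3 (−9.51 ± 0.23, edgeR adjusted p = 9.47e-16) and Upk1b (−9.50 ± 0.69). MHC II-high dura had no counts of Chst8, so its value is no measured fold. Upk1b had −11.83 or −11.81 without MHC II-high or MHC II-low replicate 4. Car12 (−10.67 ± 1.61, edgeR adjusted p = 7.18e-05) and Kcne2 (−10.56 ± 1.79, adjusted p = 0.000487) fell too, at 40.8 ± 74.8 and 38.5 ± 72.1 CPM in microglia, where replicate 3 had 153 and 147 CPM. Without that replicate their values were −7.18 and −6.65. Car12 had dura counts only in MHC II-low replicate 4 and was at least 2524-fold lower without it, so its value is no measured fold. Kcne2 had 2 dura counts and a ratio of 3685 (1020–30425) without MHC II-high replicate 2.

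H2-Aa (7.83 ± 0.64), H2-Ab1 (6.53 ± 0.50), H2-Eb1 (7.66 ± 0.63), Cd74 (6.01 ± 0.49), Mrc1 (7.66 ± 0.22), Pf4 (9.82 ± 0.38) and Ms4a7 (9.71 ± 0.31, and 10.45 without microglia replicate 1) rose, with edgeR adjusted p = 1.66e-08 or less. Tmem119 (−5.10 ± 0.18), P2ry12 (−4.44 ± 0.13) and Sall1 (−7.06 ± 0.23) fell, with edgeR adjusted p = 1.65e-13 or less. Icam2 (−0.16 ± 0.19) and Gata6 (−1.81 ± 0.89) were not called, with edgeR adjusted p = 0.481 and adjusted p = 0.092, and Gata6 was called without microglia replicate 1 (−2.21, 0.0446).

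All 18 border macrophage markers rose, with a median of 8.93 and a camera adjusted p = 0.00114, and 17 of 18 microglia markers fell, with a median of −4.56 and a camera adjusted p = 0.00314. Of 12 scavenger receptors 9 rose, among them Cd36 (9.30), with a median of 5.39 and a camera adjusted p = 0.0268, against 0.0649 with a filter of 10 CPM. Of 12 iron and heme genes 6 rose, among them Cd163 (10.95, and 12.11 without microglia replicate 1) and the biliverdin reductases Blvrb (3.42) and Blvra (1.85), with a median of 1.01 and a camera adjusted p = 0.0434. That call was lost without MHC II-high dura replicate 1 (0.0558), peritoneal replicate 1 (0.0616), 3 (0.0632) or 4 (0.0502), choroid plexus replicate 1 (0.0527) or microglia replicate 3 (0.0645), with a filter of 10 CPM (0.0742), in thinned libraries (0.0538) and after subtraction of an epithelial part (0.0715). Of 13 lipid handling genes 8 rose, among them Plin2 (3.17), and 1 fell, with a median of 2.15 and a camera adjusted p = 0.0544. That list was called without MHC II-high dura replicate 4 (0.04), peritoneal replicate 2 (0.0208), or microglia replicate 1 (0.0407) or 4 (0.0499).

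All 14 interferon response genes (median 2.72) rose, among them Rsad2 (4.10), which had 5.21 without microglia replicate 5. Of 12 proliferation genes (median 3.41) 11 rose, among them Mki67 (3.85). Of 15 cytokines (median 3.73) 10 rose, among them Ccl7 (8.22), and 4 fell. Of 12 monocyte markers (median 4.56) 7 rose, among them Lyz2 (5.69) and Ccr2 (7.04). Of 16 disease-associated microglia genes (median 1.24) 8 rose, among them Igf1 (8.11), and 4 fell. Of 10 MHC class II genes (median 3.61) 6 rose and 2 fell, and of 13 dendritic cell markers (median 1.68) 6 rose, among them Mgl2 (10.94), and 2 fell. Of 10 complement genes (median 1.27) 5 rose, among them Cfp (10.35). Camera adjusted p values were 0.612, 0.625, 0.714, 0.205, 0.431, 0.772, 0.605 and 0.387 in the order of these lists.

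Of 13 TGF-beta signalling genes (median −0.91) 1 rose and 4 fell (7 without microglia 4), among them Smad7 (−4.41) and Tgfbr1 (−2.27). Of 18 lysosome genes (median 0.06) 1 rose (2 without MHC II-high 2 or 4 or MHC II-low 3) and 5 fell, among them Ctsd (−2.60). Of 15 glycolysis genes (median −0.19) 1 rose (3 without microglia 3) and 3 fell, among them Slc2a1 (−3.12). Of 22 transcription factors (median 0.34) 9 rose and 4 fell (7 without microglia 1), of 12 core genes (median 0.22) 2 rose and 2 fell, and of 18 large peritoneal markers (median 0.31) 3 rose (5 without MHC II-low 1) and 5 fell. Of 16 cholesterol synthesis genes (median −0.37) 1 fell (0 without microglia 3, where 1 rose), and of 18 oxidative phosphorylation genes (median 0.37) 2 rose, or 1 to 6 with single libraries left out, the 6 without microglia replicate 3. Of 14 immediate early and heat shock genes (median −0.10) 3 rose and 2 fell, and of 9 chemokine receptors (median −0.31) 3 rose and 1, Cx3cr1 (−2.40), fell (2 without MHC II-high 3, peritoneal 4, choroid plexus 1 or microglia 3, 4 or 5). The adjusted p values of camera were 0.455, 0.874, 0.778, 0.946, 0.851, 0.866, 0.83, 0.741, 0.946 and 0.851 in the order of these lists.

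Of the lists of other cells, all 13 epithelium genes (median −7.90) fell, beside the 21389 summed CPM of microglia replicate 3, without which 9 fell and 1 rose. Endothelium genes fell in 7 of 8 cases, with a median of −3.03. Of 8 fibroblast genes (median 1.91) 4 rose (8 without microglia 3), or 5 adjusted over the list alone. Of 8 astrocyte genes (median −0.27) 2 rose and 3 fell, of 7 oligodendrocyte genes (median 0.01) at most 2 fell and 1 rose with all libraries or without any 1, and of 4 mesothelium genes (median −6.58) 1 rose and 3 fell. Of 6 B cell genes 2 rose, with a median of 2.37, or 2.05 with genes without counts at their bound, and of 3 mast cell genes 2 rose, with a median of 6.19, or 3.13 at the bound. EdgeR called 0 of 5 neuron genes and gave 1 higher at an unadjusted p under 0.05, DESeq2 called 1, as did edgeR without MHC II-high replicate 4, MHC II-low replicate 1 or 2 or microglia replicate 5, and the median was 0.57. In camera, adjusted p values were 0.751, 0.107, 0.625, 0.741, 0.815, 0.549, 0.772, 0.772 and 0.957 in the order of these 9 lists. The T and NK cell gene (3.93, or 1.13 at its bound), higher adjusted over the list alone or without MHC II-high replicate 1, and the neutrophil genes (median −0.35) were not called, and the erythroid gene rose (4.13). Median, mean and camera direction differed in sign for large peritoneal markers, lysosome, immediate early and heat shock genes, chemokine receptors, neurons and oligodendrocytes.

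Both comparisons with microglia were joined to ask which genes all border macrophages share. In edgeR, 1833 genes changed in the same direction in choroid plexus, MHC II-high and MHC II-low dura macrophages, each against microglia, 1174 of them higher and 659 lower. Independent gene sets of these sizes would share 36.9 higher and 15.3 lower genes. Because the same microglia libraries enter each comparison, overlap was also counted with 2 microglia libraries for choroid plexus and the other 2 for both dura groups, which gave 1023 and 993 higher and 592 and 590 lower genes for 2 such divisions. The dura comparisons still had their microglia in common. The shared genes with the largest smallest change were Tlr8, Clec12a (9.77), Slfn1, Chp2, Clec4n, a receptor for fungal sugars, and Ms4a7 (9.62) among the higher. Among the lower they were Csmd3, Upk1b, Ecscr, Myo18b, Chst8 and Adamts16, with fitted changes of 9.43 for Upk1b, 7.29 for Ecscr, 7.17 for Myo18b, 6.84 for Chst8 and 6.70 for Adamts16 against the border population where each was smallest. Csmd3 had no counts in any border population, and Upk1b, Myo18b, Chst8 and Adamts16 had none in 1 or 2 of them. Tlr8, Slfn1, Chp2 and Clec4n had 3 counts or fewer in all microglia. Without microglia replicate 1 Ms4a7 had 10.34, without choroid plexus replicate 3 Myo18b had 3 counts there and a ratio of 299 (102–1448), and without MHC II-low replicate 2 Adamts16 had 7.99. In edgeR, 564 genes were specific to microglia, and the same 6 shared lower genes, led by Csmd3, had the largest smallest change among them.

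Choroid plexus macrophages were compared with dura macrophages to ask how border macrophages differ between compartments. The dura had more of Cd209f, at 433 ± 52.1 CPM in MHC II-low and 253 ± 29.1 CPM in MHC II-high cells against 0.118 ± 0.0642 CPM in choroid plexus, and of the chemokine Ccl8, at 434 ± 165 and 494 ± 77.2 against 8.23 ± 5.62 CPM. Choroid plexus macrophages had more of the microglia genes Olfml3, at 919.7 ± 23.5 against 189 and 197 CPM, and Tmem119. Their libraries also held transcripts of choroid plexus epithelium, such as Ttr, the thyroxine carrier of cerebrospinal fluid, at 2447 ± 564 CPM against 6.39 and 2.95 CPM in the dura groups.

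In edgeR, 1795 genes changed, 1243 of them higher and 552 lower in choroid plexus macrophages. The 8 largest rises by the naming rule were those of Slc29a4, at least 2351-fold higher, Car12 (10.90 ± 1.61), Kcne2 (10.55 ± 1.79), Slc7a10 (9.74 ± 1.89), Kcnj13 (9.26 ± 1.25), Ttr (9.14 ± 1.27), Kl (8.95 ± 1.38) and Enpp2 (8.44 ± 1.13), with edgeR adjusted p = 0.00299 or less. All of them were also far above the other microglia in microglia replicate 3. Ttr lost its call when an epithelial part was subtracted (11.11, edgeR adjusted p = 0.0547). That step removes counts of Ttr itself, so the lost call does not tell their source. Car12 and Slc7a10 had dura counts only in MHC II-low replicates 4 and 2, so their values are no measured folds. Without these they were, in order, at least 2966-fold and 1338-fold higher, and Kl had 9.54 without the first. Kcne2 had 2 dura counts and a ratio of 3667 (1015–30278) without MHC II-high replicate 2. The largest falls were those of Mmp9, Cd209g and Cd209b, which had 1, 1 and 2 counts in choroid plexus and were 12802 (95% interval 2298–505662), 6114 (1097–241473) and 2655 (735–21927) times as high in the dura. Without choroid plexus replicate 1 Mmp9 and Cd209g had no counts there and were at least 3292-fold and 1572-fold lower, and Cd209b had a ratio of 4097 (735–161823). Cd209f (−11.38 ± 0.33, edgeR adjusted p = 1.78e-13), the heparanase Hpse (−6.10 ± 0.41), Nov (−6.03 ± 0.72), Lyve1 (−5.84 ± 0.26, adjusted p = 9.98e-12) and Ccl8 (−5.81 ± 0.42) followed, and Hpse had −6.91 without choroid plexus replicate 4.

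H2-Aa (2.44 ± 0.39), H2-Ab1 (2.37 ± 0.34), H2-Eb1 (2.56 ± 0.39) and Cd74 (2.12 ± 0.34) rose, with edgeR adjusted p = 0.000202 or less, but choroid plexus macrophages lay between both dura groups, with 6238 ± 826 CPM of H2-Aa against 7130 ± 283 and 186 ± 10.9 CPM. Tmem119 (2.46 ± 0.17, edgeR adjusted p = 2.39e-09) and Gata6 (3.79 ± 0.71, adjusted p = 0.000749) rose. Sall1 had 3 counts in choroid plexus, and its level in the dura was 57.5 times that (95% interval 19.7–279). Pf4 fell (−1.02 ± 0.22, edgeR adjusted p = 0.00171), and its call was lost without MHC II-high replicate 2 (−0.97) or 3 (−0.97), without MHC II-low replicate 3 (−0.99), and with a replicate block (−0.995). Mrc1 (−0.999 ± 0.15, edgeR adjusted p = 6.96e-05) was just short of 2-fold, and leaving out any 1 of 10 libraries gave a call, with −1.05 to −1.0009. These were choroid plexus replicates 1 and 2, MHC II-high replicates 1 and 4, MHC II-low replicate 1, peritoneal replicate 4 and all 4 microglia. A replicate block did so too (−1.004), as did fitting only the groups compared (−1.02) and no filter on low counts (−1.02). Icam2 (0.98 ± 0.18, edgeR adjusted p = 0.000426) was also just short and was called without MHC II-high replicate 1 (1.06) or 4 (1.01), MHC II-low replicate 2 (1.02) or 4 (1.10), or choroid plexus replicate 3 (1.01) or 4 (1.06). P2ry12 (−0.05 ± 0.13) and Ms4a7 (−0.10 ± 0.17) were not called, with edgeR adjusted p = 0.82 and adjusted p = 0.703.

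Of 18 border macrophage markers 1 rose and 10 fell, among them Folr2 (−3.80) and F13a1 (−2.98), with a median of −1.06 and a camera adjusted p = 0.0129. Of 12 scavenger receptors 5 fell, with a median of −0.89 and a camera adjusted p = 0.0147. Of 12 iron and heme genes 3 fell, Slc40a1 (−3.46), the transferrin receptor Tfrc (−2.57) and Cd163 (−1.64), with a median of −0.68 and a camera adjusted p = 0.0557. That list was called with a replicate block (0.00704) and without MHC II-high replicate 4 (0.018) or choroid plexus replicate 3 (0.0401). Of 13 lipid handling genes 3 fell, Cd36 (−1.27), Plin2 (−1.20) and Lpl (−1.09), with a median of −0.52 and a camera adjusted p = 0.108, against 0.0345 without peritoneal replicate 2. Of 12 monocyte markers 7 fell, among them Ccr2 (−1.99), with a median of −2.23 and a camera adjusted p = 0.0886. Of 13 dendritic cell markers 5 fell (and 1 rose without MHC II-low 2 or peritoneal 4), among them Cd209a (−5.04) and Mgl2 (−2.45), with a median of −0.74 and a camera adjusted p = 0.0886.

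Of 18 microglia markers (median 0.29) 6 rose, among them Olfml3 (2.25), and 3 fell, among them Crybb1 (−1.59). Of 10 MHC class II genes (median 1.52) 8 rose. Of 15 cytokines (median −0.69) 2 rose, among them Ccl4 (1.60), and 7 fell (4 and 4 without choroid plexus 1 or 4), among them Ccl24 (−2.65). Of 12 proliferation genes (median −0.87) 6 fell (3 without MHC II-low 4 or choroid plexus 3), among them Mki67 (−1.25). Of 16 disease-associated microglia genes (median −0.09) 5 fell, among them Lgals3 (−2.35), and of 10 complement genes (median −0.28) 3 fell, among them Cfp (−5.74). Of 22 transcription factors (median −0.27) 5 rose, among them Runx3 (2.22), and 3 fell. Of 18 large peritoneal markers (median −0.52) 6 rose and 2 fell, and of 14 interferon response genes (median −0.57) 1 fell (4 without microglia 5, and 0 without choroid plexus 1, 2 or 3), or 0 adjusted over the list alone. Of 14 immediate early and heat shock genes (median −0.10) 3 fell (1 without MHC II-high 3, MHC II-low 3 or choroid plexus 1 or 4), of 16 cholesterol synthesis genes (median 0.51) 3 rose, and of 13 TGF-beta signalling genes (median 0.27) 2 rose (1 without MHC II-high 1 or 3, MHC II-low 1 or choroid plexus 1 or 2). Of 15 glycolysis genes (median 0.39) 1 rose and 1 fell, of 9 chemokine receptors (median 0.52) 1 rose (2 without MHC II-high 3 or choroid plexus 1) and 1 fell, and of 18 lysosome genes (median −0.16) 1 rose. Adjusted p values from camera were 0.436, 0.216, 0.615, 0.714, 0.726, 0.612, 0.946, 0.807, 0.772, 0.723, 0.387, 0.714, 0.654, 0.294 and 0.807 in the order of these lists. Neither edgeR nor DESeq2 called a gene among 12 core genes (median −0.13, camera adjusted p = 0.757) and 18 oxidative phosphorylation genes (−0.01, adjusted p = 0.954). At an unadjusted p under 0.05 edgeR gave 2 core genes higher and 5 lower, and 5 oxidative phosphorylation genes higher and 3 lower.

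All 13 epithelium genes rose, with a median of 8.30 and a camera adjusted p = 0.437. Of 8 endothelium genes 6 rose, with a median of 2.26 and a camera adjusted p = 0.0757, against 0.0355 without MHC II-high replicate 4. Of 8 fibroblast genes (median 1.30) 4 rose (2 without MHC II-high 1, 3 or 4, MHC II-low 3 or 4 or choroid plexus 3, and 1 without choroid plexus 4) and 1 fell (0 without MHC II-high 4 or choroid plexus 1 or 2), and of 4 mesothelium genes 2 rose and 1 fell, with a median of 2.78, or 3.31 with genes without counts at their bound. At most 2 in either direction, with all libraries or without any 1, were called of 8 astrocyte genes (median −0.29), 5 neuron genes (−0.86) and 6 B cell genes (−0.76). Neither edgeR nor DESeq2 called an oligodendrocyte gene (7, median 0.40) or a mast cell gene (3, −0.63), and at an unadjusted p under 0.05 edgeR gave 2 higher and 1 lower of the first and 1 higher of the second, which it called without MHC II-low replicate 4 or microglia replicate 3. With camera, adjusted p values were 0.569, 0.615, 0.946, 0.768, 0.906, 0.815 and 0.926 from fibroblasts to mast cells. The T and NK cell gene (−3.93, or −1.07 at its bound), lower adjusted over the list alone, the neutrophil genes (median −1.63, or −0.13 at the bound) and the erythroid gene (−0.38) were not called. Median, mean and camera direction differed in sign for microglia markers, large peritoneal markers, transcription factors, oligodendrocytes and mast cells.

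**Figure D4:**
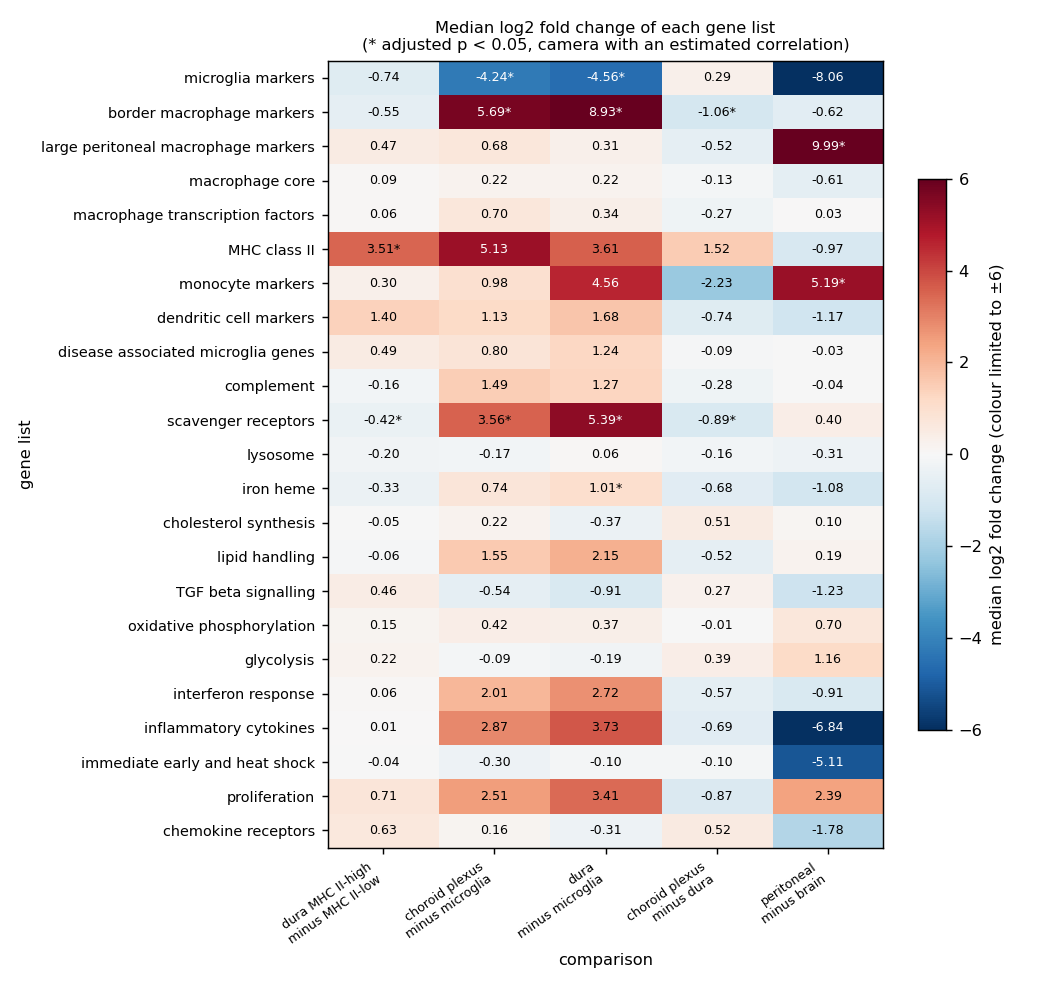
Median log2 fold change of each list of macrophage genes in each comparison, printed and coloured, with colours limited to 6 in either direction and asterisks for camera calls with an estimated correlation. Border macrophage markers have medians of 5.69 and 8.93 against microglia.

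**Figure D5:**
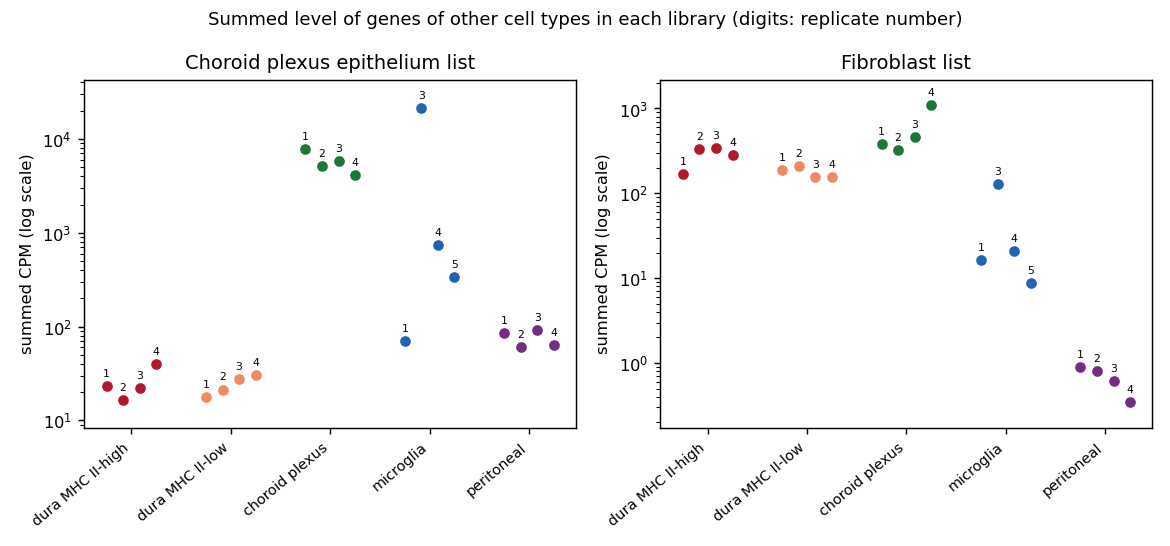
Summed CPM on a log scale of the choroid plexus epithelium and fibroblast lists in each library, with digits for the replicate number. Microglia replicate 3 has 21389 CPM of epithelium genes, and choroid plexus replicate 4 has 1090 CPM of fibroblast genes.

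Each population was compared with all others to ask which genes are specific to it. MHC II-high dura macrophages had 38 specific genes in edgeR, with the largest smallest changes for Ccr2 (3.41), the lectin Clec4b1 (2.59), Rasgrp1 (2.46), the integrin Itgax (2.01), Slamf7 (1.92) and Olfm1 (1.92). MHC II-low dura macrophages had 37, led by Nrap (2.71), Slc40a1 (2.06), Lyve1 (1.89), Cd28 (1.75), Sh3bgrl2 (1.71) and Colec12 (1.64). Choroid plexus macrophages had 104 in edgeR, 56 without choroid plexus replicate 4 and 402 without microglia replicate 3. These included Inmt (4.65), Tcf21 (4.53), Adh1 (4.24), Dpep1 (4.06) and Coch (4.03), whose levels varied between libraries, as in Coch with 128.5 ± 84.9 CPM. Choroid plexus replicate 4 also had 1090 summed CPM of fibroblast genes against 321–458 in the other choroid plexus libraries. Without it edgeR called neither Tcf21 (4.00, adjusted p = 0.0549) nor Dpep1 (3.39, 0.0844) or Coch (3.47, 0.068). Coch was also not called without MHC II-high dura replicate 3 (0.0578) or 4 (0.0518) or with a replicate block (0.0647). Without microglia replicate 3 Tcf21 and Dpep1 had 6.15 and 5.50.

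Peritoneal macrophages were compared with the brain populations to ask what sets a macrophage outside the brain apart. They had 12426 ± 1000 CPM of the lipoxygenase Alox15, 2996 ± 369 CPM of the protease inhibitor Slpi and 1082 ± 120 CPM of Icam2, against at most 1.85, 0.537 and 7.69 CPM elsewhere. The immediate early gene Fos was at 12.9 ± 3.97 CPM in peritoneal macrophages and at 12133 ± 1383 CPM in microglia, and how the cells were prepared is not stated.

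In edgeR, 4900 genes changed, 1866 of them higher and 3034 lower in peritoneal macrophages, beside a median log2 fold change over all genes of −0.11. The largest rises were those of Alox15 (15.90 ± 0.66, edgeR adjusted p = 1.56e-12), Slpi (15.55 ± 0.48), Serpinb2 (14.85 ± 0.58), Padi4 (14.02 ± 0.35), Selp (13.17 ± 0.43), Prg4 (13.06 ± 0.62) and Saa3 (12.78 ± 0.51), and of the coagulation factor F7, which had 3 counts in the brain groups and a ratio of 11476 (95% interval 3927–55650). Without MHC II-low dura replicate 4 Alox15, Slpi and Serpinb2 had 16.76, 16.19 and 16.001, without MHC II-high dura replicate 2 or choroid plexus replicate 1 Selp had 14.01 or 13.90, and without MHC II-high dura replicate 4 Prg4 had 13.66. The largest falls were those of Ttr, at least 3777-fold lower, or 1935-fold without microglia replicate 3, Chst7, at least 2944-fold, Gpr165, at least 2405-fold, Serpinf1, at least 2234-fold, Adamts1, at least 1942-fold, and Olfml3 (−13.42 ± 0.26, edgeR adjusted p = 2.76e-19). Cyr61 and Enpp2 had 1 count each in peritoneal macrophages, and their levels in the brain groups were 17857 (95% interval 3205–705320) and 14551 (2612–574754) times that. Without peritoneal replicate 3 both had no counts there and were at least 4365-fold and 3557-fold lower, and without microglia replicate 3 the ratio of Enpp2 was 7435 (1335–293684). Ttr and Enpp2 were not called when an epithelial part was subtracted (−5.25 and −7.31, both with adjusted p = 1). In edgeR, 841 genes were specific to peritoneal macrophages, with the largest smallest changes for Alox15 (12.70), Slpi (12.42), Serpinb2 (12.37), Ubash3a, Selp (11.66) and F7. Ubash3a was at 26.8 ± 7.83 CPM and had no counts in the other groups. Without MHC II-low dura replicate 4 the smallest changes of Alox15 and Slpi were 14.95 and 14.90, and without MHC II-low dura replicate 3 that of Selp was 12.45.

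Gata6 (7.58 ± 0.46), Icam2 (7.83 ± 0.14) and the chemokine Pf4 (3.59 ± 0.18) rose, with edgeR adjusted p = 2.06e-10 or less. Tmem119 (−5.43 ± 0.23), P2ry12 (−5.31 ± 0.17), Mrc1 (−4.11 ± 0.18) and Ms4a7 (−7.78 ± 0.29) fell, with edgeR adjusted p = 5.78e-14 or less, and Sall1, without counts in peritoneal macrophages, was at least 131-fold lower. These values are against the mean of the brain groups, and Mrc1 was higher in peritoneal macrophages than in microglia (47.6 and 18.2 CPM), while Ms4a7 was low in both (0.407 and 0.606 CPM). For Sall1, Pf4 and Cd74 too, libraries of the 2 sides overlap. Cd74 fell (−1.20 ± 0.35, edgeR adjusted p = 0.00608), but was short of 2-fold without peritoneal replicate 3 (−0.85, adjusted p = 0.00078). H2-Aa (−0.38 ± 0.39), H2-Ab1 (−0.74 ± 0.34) and H2-Eb1 (−0.71 ± 0.40) were not called, with edgeR adjusted p = 0.41, adjusted p = 0.0617 and adjusted p = 0.124. Without peritoneal replicate 1 H2-Ab1 (−1.22, 0.00487) and H2-Eb1 (−1.07, 0.0449) were called.

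All 18 large peritoneal macrophage markers rose, with a median of 9.99 and a camera adjusted p = 0.00154. Of 12 monocyte markers 10 rose, among them Fn1 (10.51) and Clec4e (7.25), with a median of 5.19 and a camera adjusted p = 0.0251, against 0.0502 without peritoneal replicate 4 and 0.0512 with a replicate block. Of 18 microglia markers 17 fell, among them Cx3cr1 (−11.74) and Siglech (−12.60), with a median of −8.06, or −6.62 with genes without counts at their bound, and a camera adjusted p = 0.0544. That list was called without MHC II-high dura replicate 4 (0.0434), MHC II-low dura replicate 1 (0.0427) or 2 (0.0497) or microglia replicate 3 (0.0257), and after subtraction of an epithelial part (0.0264). All 14 immediate early and heat shock genes (median −5.11) fell, among them Fos (−9.52), Egr1 (−7.80) and Fosb (−11.26). All 12 proliferation genes (median 2.39) rose, among them Rrm2 (3.58). Of 15 glycolysis genes (median 1.16) 9 rose, among them Ldha (2.40), and 1 fell (2 without peritoneal 4). Of 18 oxidative phosphorylation genes (median 0.70) 7 rose (4 without peritoneal 3). Camera adjusted p values were 0.205, 0.436, 0.377 and 0.514 for the last 4 lists in order.

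Of 15 cytokines (median −6.84) 2 rose (1 without peritoneal 3) and 11 fell, or 2 and 12 adjusted over the list alone, among them Ccl4 (−10.64). Of 12 iron and heme genes (median −1.08) 7 fell, among them Slc40a1 (−11.91). Of 13 lipid handling genes (median 0.19) 5 rose, among them Fabp4 (9.89), and 2 fell. Of 12 scavenger receptors (median 0.40) 4 rose, among them Marco (11.06), and 3 fell. Of 18 border macrophage markers (median −0.62) 4 rose and 8 fell. Of 12 core genes (median −0.61) 3 rose, among them Itgam (3.03), and 4 fell, among them Csf1r (−2.09). Of 13 TGF-beta signalling genes (median −1.23) 1 rose (0 without peritoneal 4) and 8 fell, among them Smad7 (−4.88). Of 10 complement genes (median −0.04) 4 rose, among them Cfp (6.34), and 1 fell. Of 16 disease-associated microglia genes (median −0.03) 5 rose and 4 fell, and of 22 transcription factors (median 0.03) 4 rose and 9 fell. Of 10 MHC class II genes (median −0.97) 5 fell (3 without peritoneal 3), and of 13 dendritic cell markers (median −1.17) 1 rose (2 without microglia 3) and 6 fell. Of 18 lysosome genes (median −0.31) 4 fell, of 16 cholesterol synthesis genes (median 0.10) 3 rose (and 2 fell without peritoneal 4), of 14 interferon response genes (median −0.91) 4 fell (2 without peritoneal 2 or 3, and 3 with 1 higher without microglia 5), or 2 adjusted over the list alone, and of 9 chemokine receptors (median −1.78) 1 rose and 4 fell. The adjusted p values of camera were 0.625, 0.714, 0.599, 0.714, 0.596, 0.625, 0.296, 0.866, 0.8, 0.815, 0.625, 0.387, 0.714, 0.864, 0.851 and 0.615 in the order of these lists.

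Of the lists of other cells, all 8 fibroblast genes fell, with a median of −9.93, or −9.05 with genes without counts at their bound. Endothelium genes fell in 7 of 8 cases, with a median of −7.70, or −5.68 at the bound, and of 13 epithelium genes 11 fell and 1 rose, with a median of −8.89, or −6.58 at the bound. Of 8 astrocyte genes 6 fell, with a median of −5.06, or −3.76 at the bound, and of 7 oligodendrocyte genes 5 fell, with a median of −3.76, or −2.57 at the bound. Of 6 B cell genes (median 2.64) 4 rose and 2 fell, of 5 neuron genes (median −0.94) 2 rose and 2 fell, and of 3 mast cell genes (median 0.87) at most 1 rose and 1 fell with all libraries or without any 1. EdgeR called 0 of 4 mesothelium genes and gave 0 at an unadjusted p under 0.05, DESeq2 called 1 lower, and the median was −2.38, or −1.83 at the bound. In camera, adjusted p values were 0.714, 0.338, 0.946, 0.324, 0.723, 0.946, 0.815, 0.815 and 0.726 in the order of these 9 lists. The T and NK cell gene rose (7.76), of 2 neutrophil genes (median 2.73) 1 rose, and the erythroid gene fell (−4.29). Median, mean and camera direction differed in sign for transcription factors, disease-associated microglia genes, complement, neurons and mast cells.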

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

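All tests of explanations in this part were chosen after the results were seen. Within each group of 4, a sample counted as far from the others when its gap to the nearest, divided by the range, was above Dixon's 95% critical value. Of 381 groups of values 31 had such a sample, and chance gives about 1 in 20, or 19.05. Microglia replicate 3 was that sample in 15 of them.

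Microglia replicate 3 was far above the other microglia in summed CPM of 5 lists or below them. It had 21389 CPM of epithelium genes against 70.6–738, 127 CPM of fibroblast genes against 8.66–21.1, 85.4 CPM of mesothelium genes against 2.38–4.98, 2928 CPM of oxidative phosphorylation genes against 1853–2031 and 14418 CPM of complement genes against 17530–17723. Single genes high in it were Ttr (9725 CPM against 45.0–338), Enpp2 (9054 against 15.5–316), Kl (538 against 1.00–17.2), Kcnj13 (268 against 0.815–11.3), Car12 (153 against 0.627–6.25), Kcne2 (147 against 0.878–3.24), Slc7a10 (86.9 against 0–2.95), Slc29a4 (63.5 against 0.125–5.21), Cd74 (146 against 92.0–101) and Colec12 (18.2 against 6.61–8.45). Microglia replicate 5 had 1455 CPM of interferon response genes against 155–209, and microglia replicate 1 had 1249 CPM of Adamts1 against 1086–1095.

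Among MHC II-high dura libraries, replicate 4 had 40131 CPM of border macrophage markers against 44280–44519, 91.7 CPM of astrocyte genes against 23.9–29.96, 76.3 CPM of B cell genes against 81.1–82.0 and 30.9 CPM of Hpse against 43.7–45.7. Replicate 2 had 298.6 CPM of cholesterol synthesis genes against 350.1–351.9 and 25.2 CPM of Sh3bgrl2 against 19.8–20.5, and replicate 1 had 276 CPM of Tmem119 against 202–213. Among MHC II-low dura libraries, replicate 2 had 30398564 gene counts (30.4 in units of 1e+06) against 26312505–26987657, 21.5 CPM of Nrap against 41.1–43.2 and 166 CPM of Tmem119 against 93.3–103, and replicate 4 had 2339 CPM of oxidative phosphorylation genes against 2519–2544. Among choroid plexus libraries, replicate 4 had 16351 CPM of macrophage core genes against 18181–18418 and 39.7 CPM of Slfn1 against 26.4–28.3, and replicate 3 had 955 CPM of Olfml3 against 903–912.

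In microglia replicate 3, 1308 genes were over 2-fold above every other microglia library, against 41, 29 and 121 such genes in replicates 1, 4 and 5. Choroid plexus macrophages as the source are argued against by border macrophage markers at a median of 0.00531 of their choroid plexus mean, against 0.0103 in the other microglia, and a wrong label by microglia markers at 0.811 of the level of the others. RNA or cells of choroid plexus epithelium are a candidate explanation, since 13 of 13 epithelium genes were at least 4 times above the highest other microglia library, with Ttr at 9725 CPM. For the 1243 genes higher in choroid plexus than in dura, epithelial RNA as the whole cause is argued against by 34.9% of the 917 genes compared, or 320, whose excess in microglia replicate 3 was too small. For 502 others that excess was at least as large as in choroid plexus, so epithelial RNA stays open for them.

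Of the 104 genes specific to choroid plexus macrophages, 87 were highest in choroid plexus replicate 4, where chance gives 26, against 4, 7 and 6 in the others. Library size as the cause is argued against by a ratio of gene counts to the others of 1.02. Fibroblast RNA or cells are a candidate explanation for that library, since the fibroblast list, with 1 of its 8 genes among the specific ones, was up by a median ratio of 2.81 and the specific genes by 2.44, against 0.984 for all genes. The most abundant fibroblast genes were Dcn, at 215 CPM in replicate 4 against 60.5–103.8, and Col1a1, at 207 CPM against 62.7–81.1. A difference in the macrophages of that sample stays open, as untested.

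The microglia genes Sall1, Adgrg1, Crybb1 and Fzd8 were higher in MHC II-low than in MHC II-high dura macrophages. For Sall1 a single library as the cause is argued against, since 4 of 4 MHC II-low libraries lay above all MHC II-high libraries. The same held for Adgrg1, Crybb1 and Fzd8. They were named by a rule that asks for such separation, so it tests nothing for them. Microglia in the MHC II-low libraries are argued against as the whole cause: the share of 2.34% that Sall1 needs would bring 117 counts of Csmd3 and 259.9 of Upk1b, and 0 and 14 were found, a ratio of 0.0371. At that share Tmem119 would be 128 CPM higher, and it differed by −109 CPM, while P2ry12, with 132 CPM of 135 needed, goes with such a share. Expression in the dura macrophages themselves may be the source, as a hypothesis found and tested on the same data.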

How the results depend on the processing

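Alternatives chosen after seeing the data are called added here. Under the alternatives set beforehand 286 counts stayed within 1.5 times their value, 12 rose and 10 fell beyond that. Under the added ones these numbers were 32, 2 and 0. For single genes, call and direction stayed in 16228 of their values, while 102 gained a call, 173 lost one and 3 reversed, and among the added values 1948 stayed, 43 gained, 25 lost and 5 reversed.

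With a filter of 10 CPM, which left 9477 genes, 2385 genes changed between dura and microglia, 802 between choroid plexus and dura and 2896 between peritoneal and brain macrophages, with 58 specific to choroid plexus and 21 to MHC II-high dura. Fewer genes tested lower these counts. With glmTreat the dura groups differed in 298 genes, and 47, 19 and 24 genes were specific to choroid plexus, MHC II-high and MHC II-low dura. Without a fold threshold 1530, 5914, 8091, 4639 and 9313 genes changed in the 5 comparisons in the order of the report, 1367, 229, 66, 207 and 2153 were specific to microglia, choroid plexus, MHC II-high dura, MHC II-low dura and peritoneal macrophages, and 4128 were shared. Both settings move the threshold itself. Camera with the preset correlation called 65 list tests instead of 13.

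Subtraction of the epithelial part gave 190 genes specific to choroid plexus, 103 of the 104 among them, and leaving out choroid plexus replicate 4 and microglia replicate 3 gave 292, 78 of the 104 among them. With both left out camera no longer called scavenger receptors in choroid plexus (adjusted p = 0.0757) and in dura against microglia (0.0558) or iron and heme genes in dura against microglia (0.0686), and it called microglia markers in peritoneal against brain macrophages (0.0413). Subtraction reversed Kl between dura and microglia (1.26) and F5 between choroid plexus and dura (−0.34). Between choroid plexus and microglia F5, Igfbp2 and Krt18 reversed with both libraries left out (2.77, 4.37 and 3.31) and without microglia replicate 3, and over the single libraries left out ranged from −0.77 to 2.60, −0.78 to 4.26 and −0.48 to 3.18. Beyond what each setting takes away, the cause was not tested.

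With single libraries left out, counts ranged over 435–652 for the dura groups, 2456–3370 for choroid plexus against microglia, 3906–4108 for dura against microglia, 1549–1945 for choroid plexus against dura and 4641–5003 for peritoneal macrophages. Specific genes ranged over 532–616 for microglia, 56–402 for choroid plexus, 26–45 and 29–41 for MHC II-high and MHC II-low dura and 751–925 for peritoneal macrophages. Shared genes ranged over 1724–2069 and list tests over 10–18.

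With a replicate block in all 20 libraries, 519, 2553, 3737, 1771 and 4859 genes changed in the 5 comparisons, 519, 91, 33, 38 and 825 were specific and 1790 shared, and 16 list tests were called. The block in the 8 dura libraries gave 593 genes, 441 of the 541 among them. RLE normalization, DESeq2 and thinning moved the median fold change of each comparison by at most 0.0822 on the log2 scale. DESeq2 called 718, 2821, 4163, 1913 and 5304 genes. Depth limits what can be said of genes at or under 3 counts on a side, whose folds are given as bounds or intervals.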

Other observations

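The regroupings in this part were chosen after the results were seen. To weigh chance as the source of the counts of changed genes, the libraries were regrouped, and only 1 grouping, the real one, gave as many in each case. Chance is not excluded by this, because the other groupings mix populations that differ. Such mixing raises the spread within groups and can bring their counts to 0. The dura groups differed in 541 genes, against at most 5 in the other groupings of their 8 libraries and at most 2 in those that part all 4 replicate pairs as the real one does. Choroid plexus and microglia differed in 2687 against 0, dura and microglia in 4014 against 906, choroid plexus and dura in 1795 against 1649, and peritoneal and brain macrophages in 4900 against 1536. Microglia, choroid plexus, MHC II-high dura, MHC II-low dura and peritoneal macrophages had 564, 104, 38, 37 and 841 specific genes and the border macrophages 1833 shared genes, against 0 in all other groupings drawn and in 10 simulations without any change, all in edgeR. Camera called 13 list tests against at most 1.

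One hypothesis was that choroid plexus macrophages lie on the MHC II-high side of the dura difference in genes other than MHC class II. Of 324 genes higher in MHC II-high dura, 196 lay above the dura mean in choroid plexus macrophages, or 60.5% (95% interval 54.9–65.9), and of 207 lower genes 83, or 40.1% (33.4–47.1), against 51.6% of all genes. Of these genes edgeR called 94 higher and 48 lower, and 28 higher and 59 lower, in choroid plexus than in dura. Genes are not independent replicates, and camera with an estimated correlation passed 0.05 only for the lower genes, with p values of 0.151 and 0.0247 by camera. Whether choroid plexus macrophages lie on that side cannot be told.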
